A study of Mus musculus with 87 samples.

How the data were processed

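The file used was the deposited matrix of 55401 genes and 87 libraries over 5 tissues, along with 1 file per sample. Per the submitters' processing notes, reads were aligned with STAR 2.7.6a to GRCm38 and counts were processed with DESeq2 1.28.1. Per the labels' protocols, libraries were strand-specific and made from mRNA selected by oligo(dT). The counting tool, the gene annotation and the strand setting of the count are not given in the sources used here.

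The score values were read as counts that the authors divided by a size factor per library within each tissue and rounded to whole numbers. The sources used here do not say whether the scaling was done per tissue. Recovered size factors had geometric means of 1.004, 1.007, 1.005, 1.005 and 1.006 in hypothalamus, liver, muscle, subcutaneous fat and visceral fat. The reading was checked on the values: size factors recovered from the pattern of whole numbers in each column were 0.878 to 1.2632, and a simulation with 10 columns recovered them with an error of 0.0068. All 87 columns were identical to the values of their own sample file, 0 columns were unmatched, and among 93 replicate pairs 0 were identical. The spread between replicates was 2.68 to 60.6 times counting noise.

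Estimated reads per library were 25.7 to 27.75 M in hypothalamus, 27.26 to 31.16 M in liver, 28.68 to 42.38 M in muscle, 26.37 to 28.29 M in subcutaneous fat and 26.8 to 29.35 M in visceral fat. Gene names and positions came from GENCODE M21 on GRCm38, which covered 55141 of the identifiers (99.5%). Near-identical gene copies, such as members of the Cyp3a, Sult2a, Gsta and metallothionein families, can share reads and are uncertain as single genes.

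Groups followed the labels: glucose over 300 or under 200 mg/dl and weaning weight over 14 g or under 10 g in males, and weaning weight alone in females. Comparisons were high minus low glucose and high minus low weaning weight in males, each as the mean of the differences within the other class, high minus low weaning weight in females, males minus females, and the 2 interactions. The sex comparison took the mean of the male groups minus the mean of the female groups, at equal weight per group (per weaning weight class in subcutaneous fat), so it also carried the glucose classes that only males had. In subcutaneous fat the glucose comparison used high-weight males alone and the weight comparison used high-glucose males alone. Animals, not tissues, were the independent units within a tissue, and each tissue was fitted separately.

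The comparisons, the tests on counts and a list of alternatives were fixed before the data were examined. The plan assumed raw counts and named a quasi-likelihood count model, and the deposited values were normalised and rounded, so the test used was limma 3.58.1 (linear model, moderated statistics with trend and robust options) on log2(value + 1) in R 4.3.3, with statmod 1.5.0. Genes with a value of at least 10 in as many libraries as the smallest group were kept. Adjusted p is Benjamini-Hochberg over all genes kept in a tissue, two-sided, with a threshold of 0.05. Gene lists were written from general knowledge and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and their p values were adjusted over the lists tested in a tissue. Lists with at least 5 measured members were tested.

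In simulated values of this layout, 67.2%, 62.7%, 56.7%, 3% and 37.3% of 1.5-fold changes were found in hypothalamus, liver, muscle, subcutaneous and visceral fat. Of all calls, 3.6%, 3.9%, 2.8%, 7.1% and 5.2% were false. The simulated values also held 2-fold and 4-fold changes and 1 shifted gene list. Genes were drawn independently, with no deviating library or other structure of the samples, so these rates may not hold for the real values.

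Named genes were chosen by a rule. For glucose and weaning weight these were the 6 higher and 6 lower genes with the smallest p among those with adjusted p under 0.05 and a mean of at least 1 in 1e6 of the library total, without unnamed gene models, and for sex 4 and 4. Up to 4 members with the smallest p were added from each list with a member past the threshold, along with label checks and genes fixed by tissue (Pck1, G6pc, Igfbp1, Srebf1, Fasn and Scd1 in liver, Lep, Adipoq, Slc2a4 and Ucp1 in fat, Slc2a4, Hk2, Pdk4 and Ucp3 in muscle, Agrp, Npy, Pomc and Cartpt in hypothalamus). Genes that lost their call in most fits were mostly left out of the text, and a few genes that met the rule are not reported here.

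Alternatives added after the values were seen were a pseudocount of 10, the same total per library, quantile normalization, limma without trend and robust options, and leaving out the library farthest from its group mean in liver, subcutaneous fat and visceral fat. The cutoff for a library standing apart, 1.3 times the tissue's median deviation, was also chosen after the values were seen. No library was left out of the results unless said so. Leaving 1 library out of a group of 2 left 1 there, which gives no spread for that group. Results of such fits are uncertain. This holds for high glucose, low weight males in both fats and for females in liver and visceral fat. Intronic reads, isoforms and raw reads were not available and were not examined.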

Results

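The data were 87 poly(A) RNA libraries from TallyHo/JngJ mice aged 18 weeks, a strain in which males tend to become obese and hyperglycaemic. Males were grouped by blood glucose, over 300 or under 200 mg/dl, and by body weight at weaning, over 14 g (high weight) or under 10 g (low weight). Females were grouped by weaning weight alone. There were 20 hypothalamus, 18 liver, 19 skeletal muscle, 14 subcutaneous fat and 16 visceral fat libraries, with 2 to 4 libraries per group, and subcutaneous fat had no low-glucose, low-weight males. Deposited values were counts divided by a size factor per library and rounded, with totals of 25.43 to 35.74 M counts per library. Genes tested numbered 20507 in hypothalamus, 16863 in liver, 16260 in muscle, 21096 in subcutaneous and 19640 in visceral fat. Changes are log2 differences of group means, levels are normalised counts with SD, and adjusted p is limma with Benjamini-Hochberg over all genes of a tissue unless a list test is named.

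In the livers of high-glucose males, Etnppl, Aldh3a2 and Dpyd stood higher, and Apcs, Apoa1 and Fads2 stood lower. Etnppl (chromosome 3, 130617448 to 130637521), an enzyme that breaks down phosphoethanolamine, rose by 2.31 (7430 ± 2360 against 1450 ± 427, n = 7 each, limma adjusted p = 0.000268). All 7 high-glucose livers, 4134 to 10659, lay above all low-glucose ones, 966 to 2092. Aldh3a2 (chromosome 11, 61223417 to 61267464), which oxidises fatty aldehydes, rose by 0.93 (6950 ± 1140 against 3630 ± 462, adjusted p = 0.000268). Dpyd (chromosome 3, 118562129 to 119432924), the first enzyme of pyrimidine breakdown, rose by 0.65 (16700 ± 1300 against 10800 ± 1070, adjusted p = 0.000268). Abcb4 (chromosome 5, 8893717 to 8959231), which moves phosphatidylcholine into bile, rose by 0.55 (adjusted p = 0.000681). Cryl1 rose by 0.57 (adjusted p = 0.000831). The mitochondrially encoded complex I subunit mt-Nd5 rose by 0.59 (97700 ± 7960 against 64500 ± 7090, adjusted p = 0.000831). In these 6 genes no high-glucose library overlapped a low-glucose one.

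Among liver genes that were lower with high glucose, Apcs (chromosome 1, 172893961 to 172895041), the serum amyloid P component, fell by 1.52 (1850 ± 467 against 5310 ± 1220, limma adjusted p = 6e-04). Apoa1 (chromosome 9, 46228580 to 46230466), the main protein of high-density lipoprotein, fell by 0.69 (160000 ± 16400 against 260000 ± 34300, adjusted p = 0.00119). The receptor gene Adgrf1 fell by 1.71 (45.4 ± 19.8 against 141 ± 23.7, adjusted p = 0.000837). Cpne2 fell by 0.89 (adjusted p = 0.000268). Ccdc149 fell by 1.44 (adjusted p = 0.00125). Fabp5 (chromosome 3, 10012548 to 10016607), a fatty acid carrier, fell by 2.34 (119 ± 67.5 against 585 ± 226, adjusted p = 0.00515). Ranges of the glucose classes did not overlap in any of these 6 genes, 7 libraries against 7.

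Liver genes of branched-chain amino acid breakdown were higher as a list, with 4 of 20 measured members past the threshold upward, 0 downward and 16 not passing, and 13 upward when adjusted over the list alone (median 0.205; camera adjusted p = 7.64e-11). The list call was lost with an estimated correlation (adjusted p = 0.388). Aldh6a1 (chromosome 12, 84430717 to 84451004), which also serves valine breakdown, rose by 0.37 (10900 ± 727 against 8390 ± 441, limma adjusted p = 0.00345). Pcca (chromosome 14, 122534324 to 122891100), a subunit of propionyl-CoA carboxylase, rose by 0.3 (2910 ± 132 against 2370 ± 179, adjusted p = 0.0126). Of 16 genes of glucose production 2 rose, 0 fell and 6 rose over the list alone (median 0.15; camera adjusted p = 0.00329, adjusted p = 0.388 with an estimated correlation). Fbp1 (chromosome 13, 62864753 to 62888282), fructose bisphosphatase, rose by 0.59 (33800 ± 2930 against 22500 ± 2080, adjusted p = 0.00145). Pcx (chromosome 19, 4510472 to 4621752), pyruvate carboxylase, rose by 0.43 (17200 ± 1310 against 12900 ± 1290, adjusted p = 0.00645). Pck1 and G6pc, whose products control the flow into glucose, did not pass (-0.19, adjusted p = 0.692; -0.85, adjusted p = 0.443). In all 7 high-glucose livers Aldh6a1, Pcca, Fbp1 and Pcx lay above every low-glucose liver.

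Lipogenesis genes were lower in high-glucose livers, with 0 of 20 upward, 4 downward and 7 downward over the list alone (median -0.286; camera adjusted p = 1.83e-06). That list call did not hold with an estimated correlation (adjusted p = 0.388). The list median was -0.543 within high-weight males (camera adjusted p = 1.44e-11, adjusted p = 0.184 with an estimated correlation) and -0.069 within low-weight males (camera adjusted p = 0.232). The difference between the weight classes had a median of -0.577 (camera adjusted p = 6.79e-08, adjusted p = 0.262 with an estimated correlation). Fads2 (chromosome 19, 10062765 to 10101746), a desaturase of polyunsaturated fatty acids, fell by 0.48 (12700 ± 1460 against 17500 ± 1600, limma adjusted p = 0.00454), and no high-glucose liver reached the lowest low-glucose one. Scd1 (chromosome 19, 44394455 to 44407879), which makes monounsaturated fatty acids, fell by 3.6 (37800 ± 44100 against 196000 ± 73400, adjusted p = 0.0366), and the 7 high-glucose livers, 787 to 110632, lay below the 7 low-glucose ones, 143593 to 357070. Scd1 stayed past the threshold in only 2 of 14 fits that left out 1 library, those without high glucose, high weight replicate 2 or high glucose, low weight replicate 2 (largest adjusted p = 0.097). Acacb fell by 1.45 (adjusted p = 0.0236) and was lost without high glucose, low weight replicates 1 or 3 or low glucose, low weight replicate 2 (adjusted p up to 0.0677). Fasn (-0.31, adjusted p = 0.713) and Srebf1 (0.31, adjusted p = 0.488) did not pass. Of 20 cholesterol synthesis genes 0 rose and 1 fell, with a list median of -0.26 (camera adjusted p = 1.02e-05, adjusted p = 0.431 with an estimated correlation).

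Cyp8b1 (chromosome 9, 121914356 to 121916305), which steers bile acid synthesis towards cholic acid, rose in high-glucose livers by 0.81 (16000 ± 2440 against 9130 ± 1100, limma adjusted p = 0.00153, all 7 above all 7), as the only 1 of 17 bile acid genes past the threshold. Cyp2b10 (chromosome 7, 25897620 to 25926624), a cytochrome that responds to foreign compounds, rose by 3.5 (343 ± 299 against 29.9 ± 34.8, adjusted p = 0.00691). Metal-binding Mt1 (chromosome 8, 94179082 to 94180327) rose by 2.92 (10200 ± 7900 against 931 ± 385, adjusted p = 0.0133). Mt2 rose by 2.95 (77.1 ± 69.1 against 5.43 ± 3.82, adjusted p = 0.00918). Of 22 fatty acid oxidation genes 2 rose and 1 fell (8 and 2 over the list alone; median 0.129; camera adjusted p = 0.00131, adjusted p = 0.431 with an estimated correlation). The thioesterase Acot2 rose by 1.2 (182 ± 64.7 against 79.1 ± 24.4, adjusted p = 0.01). The pantetheinase Vnn1 fell by 1.18 (16 ± 6.27 against 36.4 ± 14.8, adjusted p = 0.0136). Acute phase genes had a list median of -0.407 with 1 of 19 past the threshold downward and 6 over the list alone (camera adjusted p = 8.37e-05, adjusted p = 0.388 with an estimated correlation). Respiratory chain genes had a median of 0.139 with 0 of 22 past the threshold and 11 upward over the list alone (camera adjusted p = 2.76e-08, adjusted p = 0.388 with an estimated correlation).

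Lists of immune cells and of sex-biased genes also differed in high-glucose livers by camera, and none held with an estimated correlation. Interferon response genes had a median of -0.611 (camera adjusted p = 1.42e-06, adjusted p = 0.431 with an estimated correlation), with 0 of 20 past the threshold and 2 downward over the list alone. Macrophage markers had a median of -0.408 with 0 of 16 past the threshold (camera adjusted p = 0.000419, adjusted p = 0.431 with an estimated correlation). T and B lymphocyte markers had a median of -0.68 with 1 of 16 downward (camera adjusted p = 0.00167, adjusted p = 0.388 with an estimated correlation). Female-biased liver genes had a median of 0.424 with 1 of 20 upward (camera adjusted p = 0.000101, adjusted p = 0.388 with an estimated correlation). Male-biased genes had a median of -0.372 with 1 of 20 downward (camera adjusted p = 0.000514, adjusted p = 0.431 with an estimated correlation).

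The liver test gave 286 genes higher and 154 lower with high glucose, 440 in all. Without the trend and robust options it gave 277. Within high-weight males it called 234 genes and within low-weight males 9, while the test of the glucose difference between the weight classes called 0 genes with limma (630 at unadjusted p under 0.05). The count fell to 278 without high glucose, high weight replicate 4, to 231 and 190 without high glucose, low weight replicates 1 and 3, and to 221 and 206 without low glucose, low weight replicates 2 and 3. High glucose, high weight replicate 1 deviated from its group mean by 1.34 times the tissue's median.

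**Figure D1:**
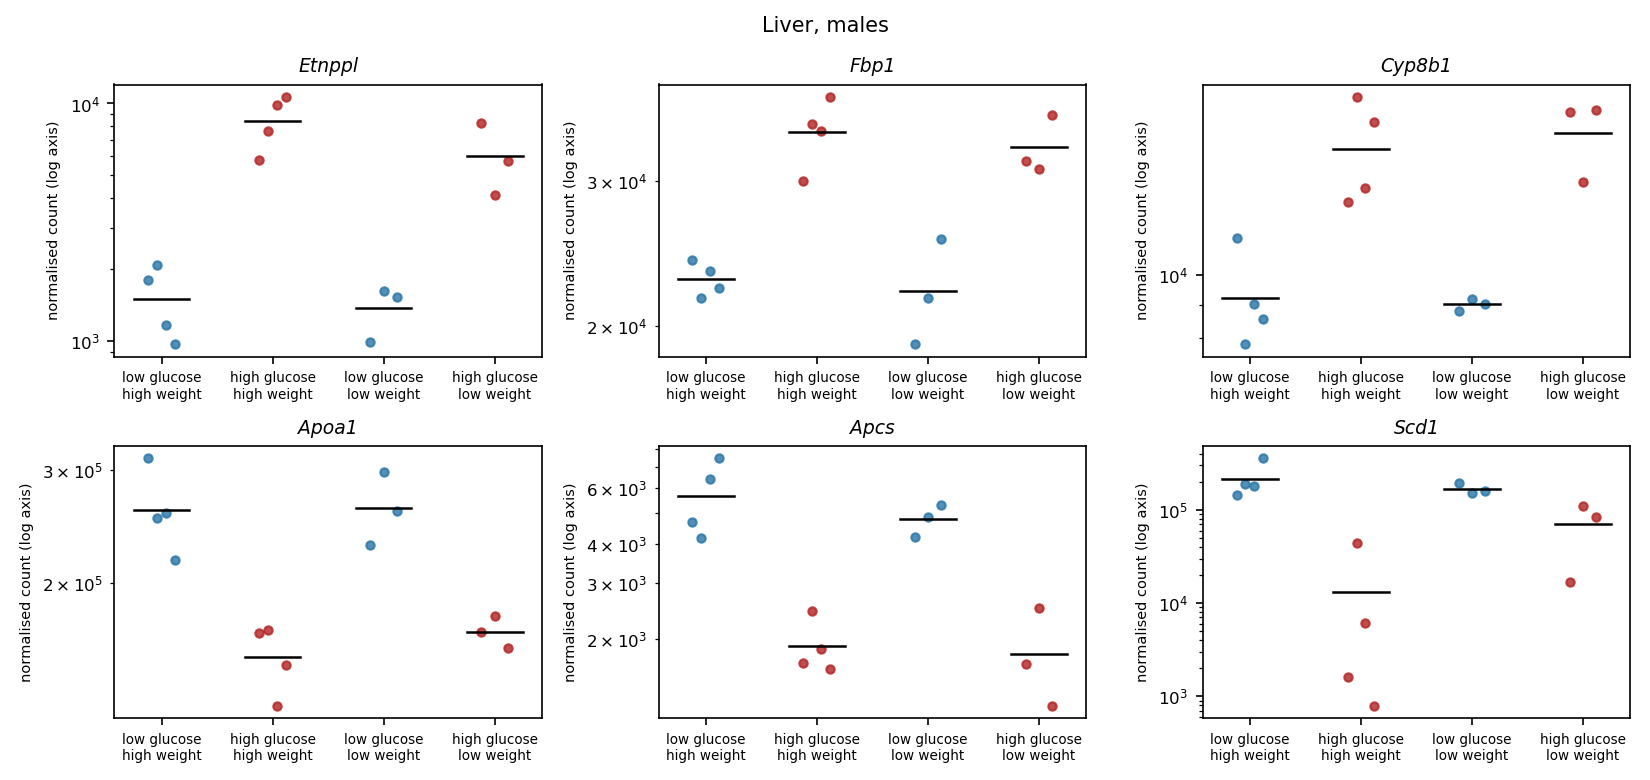
Normalised counts on a log axis of Etnppl, Fbp1, Cyp8b1, Apoa1, Apcs and Scd1 in the livers of the 4 male groups, with 1 point per library and a line at each group mean. Adjusted p of the glucose effect was 0.000268 for Etnppl, 0.00145 for Fbp1, 0.00153 for Cyp8b1, 0.00119 for Apoa1, 6e-04 for Apcs and 0.0366 for Scd1.

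In visceral fat, high-glucose males carried less transcript of lipid-making enzymes and of the growth regulators Ndn and Ret, and more of the matrix protease Mmp11 and of the T-cell receptor gene Trbc2. Fasn (chromosome 11, 120805846 to 120824547), fatty acid synthase, fell by 1.97 (15800 ± 7030 against 65700 ± 24300, n = 6 each, limma adjusted p = 0.00761). Elovl6 (chromosome 3, 129532355 to 129638495), which lengthens palmitate, fell by 1.69 (316 ± 130 against 1080 ± 266, adjusted p = 0.0047). All 6 high-glucose libraries, 7374 to 24713 for Fasn, lay below all 6 low-glucose ones, 38308 to 98306. Thrsp (chromosome 7, 97412938 to 97417730), a lipogenic nuclear protein, fell by 0.93 (6830 ± 2420 against 11700 ± 1230, adjusted p = 0.0138; 0.0559 without high glucose, low weight replicate 1). Lipogenesis genes numbered 0 upward and 9 downward of 20 measured, 10 downward over the list alone (median -0.493; camera adjusted p = 4.29e-08). The list did not pass with an estimated correlation (adjusted p = 0.142). Lep (chromosome 6, 29060220 to 29073877), leptin, differed by -1.37 (37900 ± 40400 against 85000 ± 35000) and did not pass (adjusted p = 0.0866).

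Ndn (chromosome 7, 62346569 to 62350262), an imprinted gene that restrains fat cell precursors, fell in visceral fat by 1.03 (865 ± 197 against 1850 ± 171, limma adjusted p = 0.0017). The receptor tyrosine kinase gene Ret (chromosome 6, 118151745 to 118197718) fell by 1.29 (786 ± 405 against 2040 ± 277, adjusted p = 0.00294). The small heat shock gene Hspb7 (chromosome 4, 141420779 to 141425311) fell by 2.09 (794 ± 583 against 3510 ± 1010, adjusted p = 0.00294). Gsta3 fell by 0.76 (784 ± 77.2 against 1400 ± 456, adjusted p = 0.00294). The microtubule gene Map6 fell by 0.87 (401 ± 123 against 776 ± 97.8, adjusted p = 0.00294). Lypd6 fell by 1.2 (118 ± 36.8 against 290 ± 59.8, adjusted p = 0.00349). The skeletal muscle actin gene Acta1 fell by 3.33 (166 ± 109 against 1710 ± 1040, adjusted p = 0.0149; 0.0668 without high glucose, low weight replicate 2). Mmp11 (chromosome 10, 75923222 to 75936496), a protease of the matrix metalloproteinase family, rose by 1.59 (1340 ± 370 against 414 ± 98.2, adjusted p = 0.00449). The fibrillar collagen gene Col27a1 rose by 0.79 (499 ± 52.3 against 286 ± 56.5, adjusted p = 0.00709). The G protein gene Gnal rose by 1.58 (198 ± 90.4 against 60.7 ± 7.55, adjusted p = 0.00862). Lypd1 rose by 2.15 (82.7 ± 53.3 against 12 ± 4.77, adjusted p = 0.00862). Apart from Hspb7, the ranges of the 6 high-glucose and 6 low-glucose libraries did not overlap in these genes.

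The T-cell receptor gene Trbc2 (chromosome 6, 41546730 to 41548352) rose in visceral fat by 1.01 (157 ± 39.1 against 76.7 ± 29.8, limma adjusted p = 0.0069). Gimap4, a lymphocyte GTPase, rose by 0.51 (1110 ± 172 against 742 ± 56.6, adjusted p = 0.00505). T and B lymphocyte markers numbered 2 upward and 2 downward of 16 (6 and 5 over the list alone), and the list's median of 0.22 and mean of -0.047 differed in sign (camera adjusted p = 0.843). Of 18 collagen and matrix genes 1 rose, 2 fell and 15 did not pass (median -0.32; camera adjusted p = 0.0182, adjusted p = 0.942 with an estimated correlation). Mmp14 (chromosome 14, 54431612 to 54445364) rose by 0.7 (3740 ± 655 against 2320 ± 570, adjusted p = 0.0169; 0.0597 without high glucose, low weight replicate 1). Sparc (chromosome 11, 55394500 to 55423183), a matrix protein, fell by 1.08 (87100 ± 48900 against 194000 ± 47000, adjusted p = 0.0171) and was lost without high glucose, low weight replicate 2 or low glucose, high weight replicate 2 (adjusted p up to 0.0799).

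Visceral fat gave 228 genes higher and 543 lower, 771 in all and 29.6% of them higher. With the same total per library 1107 were higher and 424 lower, 72.3% higher, as that scaling moved the all-gene median from 0.03 to 0.12, so the balance of higher and lower genes depended on the scaling. With the replicate block 173 passed (25 higher, 148 lower, 14.5% higher), with males only in the fit 511 and without the trend and robust options 453. High glucose, high weight replicate 2 deviated from its group mean by 1.39 times the tissue's median, and without it 1595 genes passed. The count was 493 and 356 without high glucose, high weight replicates 3 and 4. It was 204 without low glucose, high weight replicate 2, and 310 and 311 without low glucose, low weight replicates 1 and 2. Within high-weight males 4083 genes passed and within low-weight males 1, while the test between the weight classes gave 0 with limma (5232 at unadjusted p under 0.05). That test gave 3532 genes without high glucose, high weight replicate 2. The high glucose, low weight group held 2 libraries, so counts without either of them are not given.

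**Figure D2:**
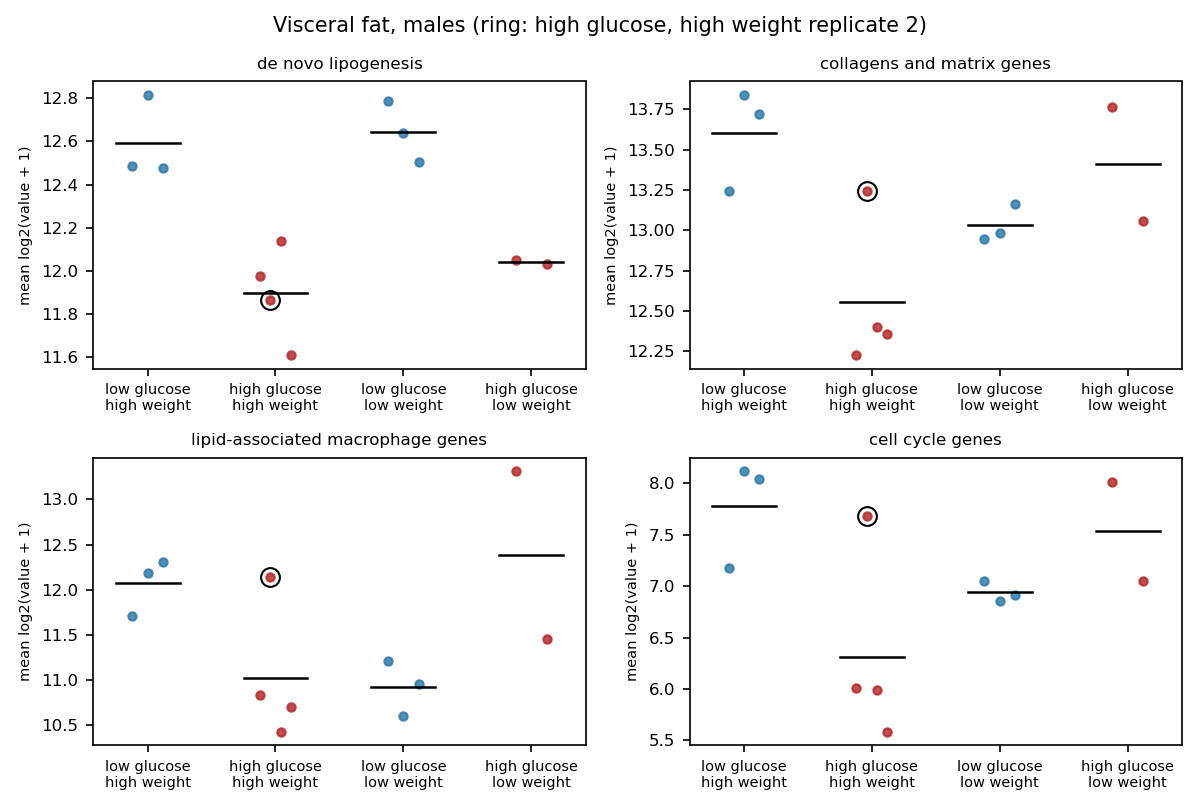
Mean log2 of normalised counts plus 1 over the members of 4 gene lists (lipogenesis, collagens and matrix, lipid-associated macrophage genes, cell cycle) in visceral fat of the 4 male groups, 1 point per library. A ring marks high glucose, high weight replicate 2, the library at 1.39 times the median deviation.

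**Figure D3:**
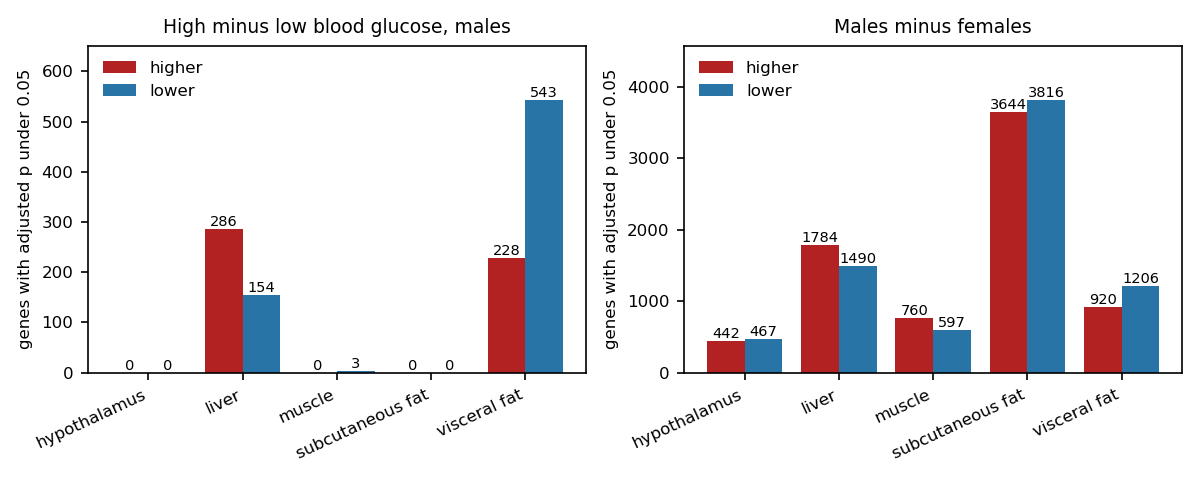
Number of genes with adjusted p under 0.05 in each tissue, higher in red and lower in blue, for high minus low glucose in males on the left and for males minus females on the right. Bars of the left panel stand at 286 and 154 in liver and at 228 and 543 in visceral fat.

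Skeletal muscle of high-glucose males held less Ivd (chromosome 2, 118861954 to 118882909), isovaleryl-CoA dehydrogenase of leucine breakdown, by -0.48 (2540 ± 419, n = 7, against 3590 ± 403, n = 6; limma adjusted p = 0.0155). It was lost without high glucose, low weight replicates 1 or 2, low glucose, high weight replicate 2 or low glucose, low weight replicates 1 or 2 (adjusted p up to 0.091). The methyltransferase gene Mettl21e fell by 0.94 (563 ± 128 against 1080 ± 155, adjusted p = 0.0333; past the threshold in 4 of 13 fits without 1 library, largest adjusted p = 0.132). Slc2a4, the insulin-responsive glucose transporter, did not pass (-0.24, 11500 ± 988 against 13700 ± 467, adjusted p = 0.123), nor did Hk2 (-0.28, adjusted p = 0.394) or Pdk4 (-0.24, adjusted p = 0.919). Branched-chain breakdown had 0 of 20 genes upward, 1 downward and 6 downward over the list alone (median -0.146; camera adjusted p = 1.2e-09, adjusted p = 0.381 with an estimated correlation). The respiratory chain had 0 of 22 past the threshold (median -0.174; camera adjusted p = 1.17e-13, adjusted p = 0.381 with an estimated correlation). Muscle gave 0 genes higher and 3 lower. The count was 5 without high glucose, high weight replicate 1 and 1 without high glucose, low weight replicate 1 or 2 or low glucose, low weight replicate 1 or 2, and the same total per library gave 3 higher and 3 lower.

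In subcutaneous fat, with 3 libraries against 3, Lep (-1.05), Adipoq (0.01), Slc2a4 (0.14) and Ucp1 (0.81) did not pass (limma adjusted p = 1 for each), and 0 genes passed in all (243 at unadjusted p under 0.05). Erythrocyte markers there had a list median of -1.321 (camera adjusted p = 1.01e-14, adjusted p = 0.104 with an estimated correlation). In simulated data of this size 20.9% of genes changed 2-fold were found in subcutaneous fat, against 88.1% in hypothalamus, 73.1% in liver, 79.1% in muscle and 68.7% in visceral fat. In the hypothalamus, Pomc (chromosome 12, 3954951 to 3960642), the precursor of satiety peptides, differed by -0.58 (596 ± 162 against 913 ± 188, n = 7 each, adjusted p = 0.653). The hunger peptide gene Npy differed by 0.47 (426 ± 141 against 303 ± 59.7, adjusted p = 0.778). Agrp (0.16, adjusted p = 0.967) and Cartpt (-0.12, adjusted p = 0.961) did not pass either, and limma gave 0 genes (1262 at unadjusted p under 0.05). Without high glucose, high weight replicate 1, low glucose, high weight replicate 2 or low glucose, low weight replicate 1 the hypothalamus count was 2, 1 and 3. The test of the glucose difference between the weight classes gave 0 genes with limma in hypothalamus (1663 at unadjusted p under 0.05; 1 gene without low glucose, high weight replicate 2) and in muscle (473).

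High against low weaning weight in males separated 1 gene at 18 weeks. Slc25a48, a mitochondrial carrier gene, was the only gene past the threshold, in the hypothalamus (1.78, limma adjusted p = 0.0437), and it stayed past it in 2 of 14 fits without 1 library. In liver, Scd1 (-1.68, adjusted p = 0.894) did not pass. Neither did Lep (-0.84, adjusted p = 0.723) or Adipoq (-0.12, adjusted p = 0.85) in visceral fat, Lep in subcutaneous fat (0.61, adjusted p = 1), Slc2a4 in muscle (-0.11, adjusted p = 1) or Pomc in hypothalamus (-0.2, adjusted p = 0.966). Interferon response genes had a liver list median of 0.482 (camera adjusted p = 4.75e-06, adjusted p = 0.785 with an estimated correlation). T and B lymphocyte markers had a median of 0.33 in visceral fat with 3 upward over the list alone (camera adjusted p = 0.00534, adjusted p = 0.892 with an estimated correlation). Of 15 genes in a list of epididymis and mesothelium markers, only 6 were measured in visceral fat. Their median was 1.191 (camera adjusted p = 0.00705, adjusted p = 0.892 with an estimated correlation). Which of the 2 tissues these transcripts came from was not tested. With limma 0 genes passed in liver (892 at unadjusted p under 0.05), muscle (492), subcutaneous fat (165) and visceral fat (1401). Liver gave 1 without high glucose, high weight replicate 4 or low glucose, low weight replicate 3, and visceral fat gave 10 without high glucose, high weight replicate 2 and 1 without low glucose, low weight replicate 1.

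Between females of high and low weaning weight 0 genes passed with limma in every tissue. At unadjusted p under 0.05 there were 1021 in hypothalamus, 707 in liver, 458 in muscle, 485 in subcutaneous and 344 in visceral fat. Groups held 2 libraries each in liver and visceral fat and 3 each elsewhere. The simulation covered glucose in males alone, so the size of change that could be found here is not known. Liver Scd1 differed by -0.71 (127000 ± 72500 against 246000 ± 221000, n = 2 each, adjusted p = 1), Lep in visceral fat by 0.16 (adjusted p = 1), Hk2 in muscle by 0.26 (adjusted p = 1) and Pomc by 0.02 (adjusted p = 0.997). Endothelial markers had a liver median of 0.464 with 7 upward over the list alone (camera adjusted p = 3.09e-11, adjusted p = 0.121 with an estimated correlation). Lipogenesis genes had a visceral fat median of -0.373 (camera adjusted p = 3.62e-09, adjusted p = 0.108 with an estimated correlation). T and B lymphocyte markers had a visceral fat median of 0.826 (camera adjusted p = 1.4e-09, adjusted p = 0.198 with an estimated correlation). Without low-weight female replicate 3 the hypothalamus gave 2 genes, and without low-weight female replicate 1 muscle gave 1. The test of whether the weight effect differed between the sexes gave 0 genes in each tissue (694, 528, 392, 294 and 471 at unadjusted p under 0.05 in hypothalamus, liver, muscle, subcutaneous and visceral fat). It gave 2 in hypothalamus without low-weight female replicate 3. The same total per library moved its all-gene median in subcutaneous fat from 0.03 to -0.1.

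Males and females differed in sex-linked genes in each tissue and in many genes of liver and fat. Xist (chromosome X, 103460366 to 103483254), which silences 1 X chromosome in females, stood at 4.07 ± 2.37 (n = 14) in males and 16200 ± 1640 (n = 6) in females in hypothalamus. It stood at 6 ± 4.4 (n = 14) and 22000 ± 4730 (n = 4) in liver and 2 ± 1.41 (n = 13) and 4410 ± 333 (n = 6) in muscle. In subcutaneous fat it stood at 6.38 ± 3.11 (n = 8) and 23900 ± 1230 (n = 6), and in visceral fat at 3.83 ± 2.55 (n = 12) and 21100 ± 1530 (n = 4). Uty (chromosome Y, 1096861 to 1245759), a Y-linked demethylase gene, stood at 852 ± 74.8, 488 ± 43, 763 ± 74.4, 866 ± 76.5 and 890 ± 76.8 in males of the 5 tissues in the order above and at most 0.833 on average in females. The sex label of each library fitted its values. Females had no glucose class, so each male mean was taken over the male groups.

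Female livers carried cytochromes and sulfotransferases that were almost absent from male livers, and male livers carried more of other steroid and glutathione enzymes. Of 20 female-biased liver genes 0 were higher in males, 19 lower and 20 lower over the list alone (median -8.8; camera adjusted p = 1.83e-39), and this call held with an estimated correlation (adjusted p = 0.00118). Cyp3a41a (chromosome 5, 145694049 to 145720136) stood at 54.9 ± 11.5 in males (n = 14) and 44400 ± 10600 in females (n = 4; -9.65, limma adjusted p = 1.1e-18). Its near-identical neighbour Cyp3a41b stood at 29.2 ± 6.3 and 20400 ± 4730, and reads of the pair cannot be told apart with certainty. Sult3a1 (chromosome 10, 33857721 to 33879532), a sulfotransferase, was listed at 0.0714 ± 0.267 in males and 2830 ± 638 in females. Of 20 male-biased genes 16 were higher in males, 0 lower and 19 higher over the list alone (median 2.725; camera adjusted p = 7.07e-21, adjusted p = 0.124 with an estimated correlation). Cyp2d9 (chromosome 15, 82433437 to 82456845), a steroid hydroxylase, rose by 3.36 (43400 ± 7100 against 4400 ± 1550, adjusted p = 9.84e-13). Gstp1 (chromosome 19, 4035407 to 4037985), a glutathione transferase, rose by 3.59 (60700 ± 12400 against 5000 ± 673, adjusted p = 3.09e-11). Lama3 rose by 3.38 (410 ± 78.2 against 39.2 ± 10.6, adjusted p = 2.61e-11). The elongase Elovl3 rose by 5.92 (2800 ± 947 against 43 ± 7.87, adjusted p = 5.42e-08).

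Lipogenesis genes were lower in male livers, 0 upward and 10 downward of 20 and 11 downward over the list alone (median -0.65; camera adjusted p = 8.57e-07). That list did not pass with an estimated correlation (adjusted p = 0.292). Fads1 (chromosome 19, 10182888 to 10196877), a desaturase, fell by 0.66 (11700 ± 1360 against 18400 ± 1530, limma adjusted p = 2.01e-06). Acly (chromosome 11, 100476353 to 100528000), which makes acetyl-CoA from citrate, fell by 1.01 (6300 ± 1580 against 12400 ± 1870, adjusted p = 0.000303). The lipid droplet gene Pnpla3 fell by 4.56 (11.7 ± 22.9 against 177 ± 124, adjusted p = 0.000227). Cholesterol synthesis genes numbered 0 upward and 11 downward of 20 and 12 downward over the list alone (median -0.41; camera adjusted p = 2.81e-06, adjusted p = 0.585 with an estimated correlation). The sterol sensor gene Insig1 fell by 0.85 (6420 ± 1380 against 11600 ± 1550, adjusted p = 0.000686). Cyp7b1 (chromosome 3, 18071950 to 18243338), an oxysterol hydroxylase, rose in males by 2.73 (7980 ± 3250 against 1140 ± 265, adjusted p = 6.9e-05). Alas2 (chromosome X, 150547375 to 150570638), of haem synthesis, rose by 2.1 (708 ± 123 against 165 ± 33.4, adjusted p = 2.41e-08). Erythrocyte markers, a measure of blood in the sample, numbered 2 upward and 0 downward of 8 (median 0.765; camera adjusted p = 0.000832, adjusted p = 0.585 with an estimated correlation). The collagen gene Col5a2 (chromosome 1, 45374321 to 45503282) fell by 4.32 (287 ± 127 against 5420 ± 1300, adjusted p = 6.73e-07). Among acyl-CoA genes Vnn1 fell by 2.09 (adjusted p = 1.45e-05). Ehhadh fell by 0.53 (5860 ± 699 against 8540 ± 1660, adjusted p = 0.000769).

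Liver gave 1784 genes higher and 1490 lower in males, 3274 in all. Without high-weight female replicate 2 it gave 2001 and without low-weight female replicate 1 it gave 2116.

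Female subcutaneous fat carried epithelial transcripts, of a kind made in mammary gland, and male subcutaneous fat had more lymphocyte transcripts. All 16 epithelial genes were lower in males (median -9.461; camera adjusted p = 1.31e-20), and the call held with an estimated correlation (adjusted p = 0.00437). Epcam (chromosome 17, 87635979 to 87651129), an epithelial adhesion gene, stood at 106 ± 24.7 in males (n = 8) and 9740 ± 2770 in females (n = 6). The keratin gene Krt18 (chromosome 15, 102028180 to 102032027) stood at 7.5 ± 5.73 and 8810 ± 3190, and the transcription factor gene Tfap2c at 0.125 ± 0.354 and 2610 ± 882. Serpinb5 (chromosome 1, 106861173 to 106883348), a serpin of myoepithelium, was listed at 0 in every male library and at 593 ± 189 in females. All 16 lymphocyte markers were higher in males (median 1.986; camera adjusted p = 9.1e-05, adjusted p = 0.783 with an estimated correlation). Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of antigen presentation, rose by 1.15 (54100 ± 9620 against 25200 ± 8900, limma adjusted p = 0.00378). The lymphocyte genes Ighm (1.5, adjusted p = 0.0115) and Cd4 (1.75, adjusted p = 0.0141) were lost without high glucose, low weight replicate 2 (adjusted p = 0.073 and 0.0647).

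Of 20 lipogenesis genes in subcutaneous fat, 0 were higher in males, 9 lower and 11 not passing, with 10 lower over the list alone (median -0.777; camera adjusted p = 0.0046, adjusted p = 0.783 with an estimated correlation). Female samples also held the epithelial transcripts described above, so sex differences in this tissue cannot be told apart from its cell composition. Fads2 fell by 2.56 (771 ± 95.8 against 4740 ± 1570, limma adjusted p = 2.14e-06). Acly fell by 1.42 (4480 ± 951 against 11700 ± 3280, adjusted p = 0.000233). Acot1 (chromosome 12, 84009490 to 84018371), an acyl-CoA thioesterase, fell by 6.57 (65.6 ± 15.1 against 7530 ± 4250, adjusted p = 1.06e-07), among 2 upward and 7 downward of 23 fatty acid oxidation genes (camera adjusted p = 0.00926, adjusted p = 0.783 with an estimated correlation). Spp1 (chromosome 5, 104435118 to 104441050), osteopontin, which macrophages and milk-forming epithelium both make, fell by 8.79 (36.6 ± 24.2 against 41500 ± 48400, adjusted p = 0.000105). Lipocalin 2, Lcn2 (chromosome 2, 32384633 to 32388252), fell by 7.07 (158 ± 141 against 20400 ± 23200, adjusted p = 3.14e-05). The milk lipase gene Cel stood at 1.62 ± 2.83 in males and 10600 ± 11100 in females. High-weight female replicate 3 deviated from its group mean by 1.56 times the tissue's median. Subcutaneous fat gave 3644 genes higher and 3816 lower, 7460 in all, and 3623 (1147 higher and 2476 lower) without high glucose, low weight replicate 2. The same total per library moved the all-gene median from 0.02 to 0.11.

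In visceral fat of males, genes of lipid-laden macrophages and of fatty acid oxidation stood higher than in females. Lipid-associated macrophage genes numbered 8 upward, 0 downward and 6 not passing of 14, and 9 upward over the list alone (median 1.01; camera adjusted p = 4.35e-07, adjusted p = 0.539 with an estimated correlation). Gpnmb (chromosome 6, 49036546 to 49070929), a marker of such macrophages, rose by 3.63 (9320 ± 10900, n = 12, against 648 ± 366, n = 4; limma adjusted p = 0.000496). Mmp12 (chromosome 9, 7344381 to 7369499), macrophage elastase, rose by 3.57 (10900 ± 13400 against 920 ± 756, adjusted p = 0.00121). The proton pump subunit Atp6v0d2 rose by 3.28 (1050 ± 968 against 101 ± 59.1, adjusted p = 0.000432). Of 21 fatty acid oxidation genes 6 rose, 0 fell and 15 rose over the list alone (median 0.51; camera adjusted p = 3.73e-09, adjusted p = 0.234 with an estimated correlation). Slc25a20 (chromosome 9, 108662088 to 108684641), the carnitine carrier, rose by 0.55 (1640 ± 161 against 1120 ± 90.7, adjusted p = 0.000481). Thermogenic genes numbered 4 upward and 0 downward of 14 (median 0.7; camera adjusted p = 0.0041, adjusted p = 0.539 with an estimated correlation). Ppargc1a (chromosome 5, 51454250 to 51567726), a coactivator of mitochondrial genes, rose by 1.71 (173 ± 133 against 38.2 ± 2.22, adjusted p = 0.002). The lipid droplet gene Cidea rose by 2.1 (83.2 ± 39.5 against 17.5 ± 5.45, adjusted p = 0.0065).

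Lipogenesis genes of visceral fat moved both ways between the sexes, 2 upward and 6 downward of 20 (camera adjusted p = 0.0208, adjusted p = 0.641 with an estimated correlation). Gpam (chromosome 19, 55067268 to 55127238), the first enzyme of triglyceride synthesis, fell by 1.15 (4930 ± 1660 against 9910 ± 799, limma adjusted p = 0.000516). Acly fell by 1.09 (adjusted p = 0.00064). Scd1 rose by 1.37 (553000 ± 191000 against 212000 ± 54100, adjusted p = 0.00271). Acacb rose by 1.83 (4440 ± 3420 against 976 ± 190, adjusted p = 0.00156). Hoxa11 (chromosome 6, 52242106 to 52245810), a homeobox gene of the posterior body, was listed at 0 in male visceral fat and at 136 ± 35.1 in females. Plekha6 fell by 2.54 (458 ± 110 against 2620 ± 490, adjusted p = 3.17e-08). The parathyroid hormone receptor gene Pth1r fell by 1.91 (446 ± 117 against 1620 ± 433, adjusted p = 5.58e-08). Visceral fat gave 920 genes higher and 1206 lower, 2126 in all. It gave 1007 and 920 without high-weight female replicates 1 and 2 and 1211 and 1142 without low-weight female replicates 1 and 2.

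Male muscle libraries had less transcript of slow fibre genes than female ones, apart from 1 male library named below. Sample titles say only muscle, so a difference in the part of muscle taken cannot be told apart from sex. Of 12 slow fibre genes 0 rose, 3 fell and 9 fell over the list alone (median -1.833; camera adjusted p = 7.57e-07, adjusted p = 0.424 with an estimated correlation). Casq2 (chromosome 3, 102086415 to 102146514), the calcium store of slow and heart muscle, fell by 0.99 (189 ± 61.3, n = 13, against 371 ± 87.3, n = 6; limma adjusted p = 0.00388). Myl2 (chromosome 5, 122100951 to 122113472), the slow myosin light chain, fell by 5.02 (139 ± 356 against 1060 ± 454, adjusted p = 0.0104). Csrp3 fell by 2.21 (527 ± 317 against 2330 ± 1800, adjusted p = 0.0145). Low glucose, low weight replicate 2 had a slow fibre score of 10.289 against 5.588 to 7.552 in the other males and 7.965 to 9.997 in females. Adipocyte markers in muscle numbered 0 upward and 5 downward of 12 and 10 downward over the list alone (median -1.626; camera adjusted p = 9.49e-07, adjusted p = 0.308 with an estimated correlation). Car3 (chromosome 3, 14863512 to 14872523), a carbonic anhydrase of fat and muscle, fell by 1.89 (9200 ± 4360 against 30800 ± 3120, adjusted p = 0.000869). Bckdhb (chromosome 9, 83925145 to 84124240), of branched-chain keto acid breakdown, fell by 0.62 (739 ± 96.5 against 1140 ± 98.1, adjusted p = 2.12e-06). Tbc1d1 (chromosome 5, 64156305 to 64351486), which regulates glucose transporter traffic, fell by 1.1 (1240 ± 269 against 2600 ± 297, adjusted p = 0.000206). Actr3b (chromosome 5, 25759997 to 25850688), of actin branching, rose by 2.1 (601 ± 124 against 141 ± 28.3, adjusted p = 3.14e-12). Muscle gave 760 genes higher and 597 lower, 1357 in all.

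In the hypothalamus, the X-linked genes Eif2s3x, Kdm6a and Ddx3x and the signalling genes Npy2r and Nms were lower in males. The X-linked Eif2s3x (chromosome X, 94188707 to 94212862) fell by 0.63 (3050 ± 82, n = 14, against 4710 ± 148, n = 6; limma adjusted p = 2.24e-16). Kdm6a fell by 0.56 (799 ± 37.9 against 1170 ± 19.3, adjusted p = 1.44e-12). Ddx3x fell by 0.41 (7210 ± 242 against 9550 ± 338, adjusted p = 3.91e-12). Npy2r (chromosome 3, 82538383 to 82548084), a receptor of neuropeptide Y and peptide YY, fell by 0.52 (452 ± 57.2 against 656 ± 111, adjusted p = 0.000115). Nms (chromosome 1, 38939149 to 38950276), neuromedin S, fell by 0.9 (27.6 ± 9.82 against 50.3 ± 9.54, adjusted p = 0.0107). Feeding peptide genes numbered 0 upward and 3 downward of 22 and 9 downward over the list alone (median -0.372; camera adjusted p = 9.92e-06, adjusted p = 0.357 with an estimated correlation). Genes that mark the hypothalamic region, which vary with dissection, had a median of -0.231 with 0 of 16 past the threshold (camera adjusted p = 0.000871, adjusted p = 0.357 with an estimated correlation). The clock gene Per1 (chromosome 11, 69095217 to 69109960) rose by 0.32 (2560 ± 267 against 2020 ± 132, adjusted p = 0.00277). Hypothalamus gave 442 genes higher and 467 lower, 909 in all, and 2148 without low glucose, high weight replicate 4. Without the trend and robust options 220 passed (101 higher, 119 lower) and without a filter on low values 586. It gave 588 without high glucose, high weight replicate 4, 521 without high glucose, low weight replicate 2 and 516 without low glucose, low weight replicate 1. Without high-weight female replicate 1 it gave 265, and without low-weight female replicates 2 and 3 it gave 403 and 272.

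**Figure D4:**
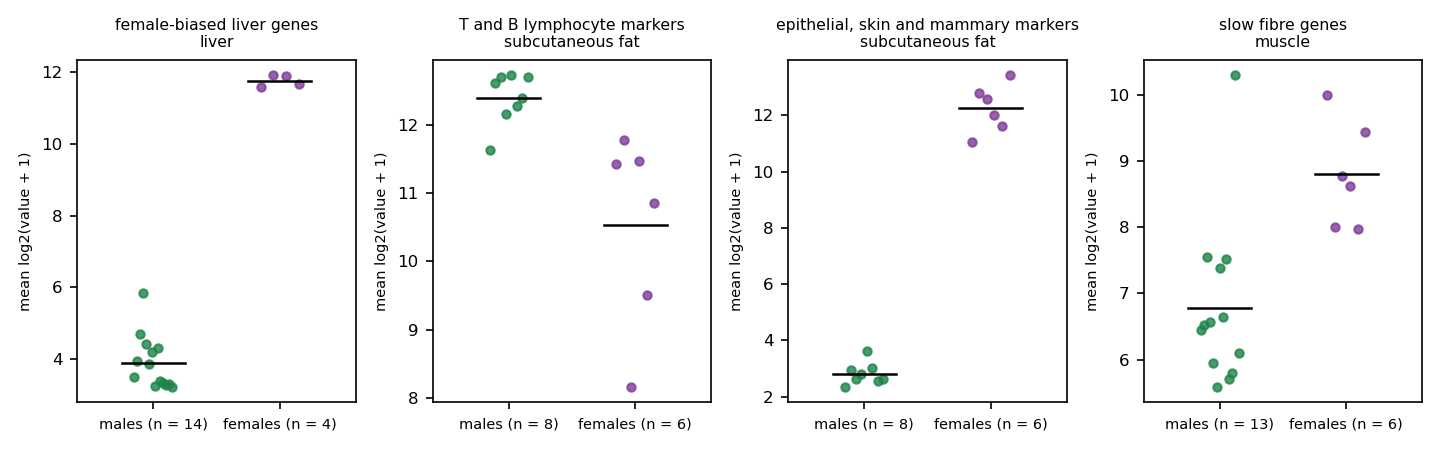
Mean log2 of normalised counts plus 1 over the members of 4 gene lists (female-biased liver genes in liver, lymphocyte and epithelial markers in subcutaneous fat, slow fibre genes in muscle), 1 point per library, males in green and females in purple. List medians of males minus females were -8.8, 1.986, -9.461 and -1.833.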

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

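Tests chosen after the result was seen were the shuffles of code numbers for the interferon genes, mammary dilution and fewer adipocytes for the lymphocyte markers, female RNA and acute phase for the female-biased liver genes, and the liver against muscle comparison of branched-chain breakdown. The tests of shared animals, depth, lymph node and hepatocytes and all splits of libraries were first written down before their values were computed, and the shared-animal and hepatocyte tests were changed afterwards, as was the adipocyte test.

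Interferon response genes moved together across tissues in libraries that share a group and a code number, with a mean Pearson r of 0.65 between tissues. Chance order of the numbers gave a share of 1e-05, the smallest that 100001 orders can give, with 0.6 as the highest shuffled mean, so chance order is excluded. Sequencing depth reached an absolute r of 0.5 in 0 of 5 tissues and is excluded too. If tissues with the same code number came from 1 animal, genes outside the list should also deviate together. They did, with a mean correlation of 0.039 for the same number and -0.017 for other numbers. The difference was 0.056 (permutation p = 1e-05, again the smallest possible, highest shuffle 0.035). A shared animal would give this, but no label names the animal, and an interferon state of single animals was not tested. This test was first run with the replicate numbers of the titles and was changed to the numbers in the sample codes, which differ for 13 libraries, after its values were seen (with the title numbers, mean r 0.56 and difference 0.04).

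Lymphocyte markers were higher in male than in female subcutaneous fat. Lymph node genes (Cxcl13, Ccl21a, Ccl19, Cr2, Fcer2a, Chst4, Madcam1, Glycam1; 5 broader lymphocyte genes were dropped from the list before the test) had a median difference of 2.29, past the value of 1 that lymph node tissue in the male samples would bring. Only Ccl19 (2.24, adjusted p = 0.0375) and Glycam1 passed on their own, Glycam1, which mammary gland also makes, going the other way at -2.27, and Madcam1, of lymph node venules, did not differ (0, adjusted p = 0.993). Mammary tissue diluting other cell types in females cannot account for the whole difference by the markers tested. The highest median of macrophage, endothelial and adipocyte markers lay -1.74 from the lymphocyte median. Erythrocyte markers, outside that test, had a median of 1.11, so dilution as part of the cause stays open. More lymph node tissue in the male samples stays open, against the value of Madcam1. Fewer adipocytes in males would lower adipocyte markers, but their median was 0.25, above 0. As 0.25 was smaller than the interquartile range of the members (0.42), the adipocyte test does not decide. That range was added to the test after the value was seen. Macrophage and endothelial medians of 0.17 and 0.1, against 1.99 for lymphocytes, argue against fewer adipocytes as the whole cause. The erythrocyte median of 1.11 lay in between.

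Female-biased genes were highest among male livers in high glucose, high weight replicates 3 and 4, with scores of 4.71 and 5.85. The other high-glucose livers scored 3.49 to 4.41. Low-glucose livers scored 3.22 to 3.39, apart from low glucose, high weight replicate 2 at 4.32. The causes below were tested for replicates 3 and 4 alone, not for the glucose class. RNA of a female liver is excluded, since Xist reached at most 0.029 of the level needed. An acute phase response alone did not bring high female-biased scores. Of 2 other male livers with as high an acute phase score, 2 had a female-biased score at or below the male median. Both were low-glucose livers, so the test cannot exclude an acute phase response acting within high glucose. Hepatocyte genes had median differences of -0.19 and -0.17 from the other male livers. Both lay above -0.2, the limit first written for no loss of hepatocytes, and above -0.5, the limit for a loss. As -0.19 lay nearer to -0.2 than the spread of the other livers (SD 0.11), fewer hepatocytes could not be told from none missing. That spread was added to the test after the value was seen. Male-biased scores of these 2 libraries, 12.78 and 11.81, were the lowest among male livers. Both lists hold liver genes, so their opposite moves argue against a loss of hepatocytes alone.

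Library labels were split anew and each split was tested like the real one. For glucose in males, the liver count of 440 was reached by 1 of 100 splits, the real one itself (highest other 2), so chance is unlikely. A share of 1 in 100 is the smallest that these splits can give. In visceral fat 4 of 100 splits reached 771, the highest at 3508. In muscle 4 of 100 reached 3, the highest at 46. Splits that call several times the real count point to a structure of the samples, and the visceral fat split with 3508 placed high glucose, high weight replicate 2 with the low-glucose, high-weight libraries. In hypothalamus the real count was 0, which 100 of 100 splits must reach (highest 1032), so the splits test nothing there. Subcutaneous fat allowed only 10 splits, too few to tell (real 0, highest 2).

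Where the real count was 0, the splits again test nothing. For the interaction of glucose and weaning weight this held for 100 of 100 splits in hypothalamus (highest 590), liver (261), muscle (4) and visceral fat (2367). For weaning weight in males, 3 of 100 splits reached the single hypothalamus gene (highest 301), and 100 of 100 reached 0 in liver (highest 25), muscle (219) and visceral fat (3308). For weaning weight in females, the 10 splits of hypothalamus (highest 0), muscle (0) and subcutaneous fat (16) were too few. For weaning weight by sex, 100 of 100 splits reached 0 in hypothalamus (highest 0) and muscle (396). For sex, only 1 of 100 splits, the real one, reached the count in hypothalamus (909, highest other 2), liver (3274, 618), muscle (1357, 411), subcutaneous fat (7460, 2496) and visceral fat (2126, 8). Chance is unlikely there, at the smallest share that 100 splits can give.

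Single libraries stood apart within their group in 20 of 243 groups of values (genes not reported here left out), where chance flags about 1 in 20 groups. In the hypothalamus of high glucose, high weight replicate 2, mean scores were 7.14 for interferon response, 12.01 for respiratory chain and 9.03 for endothelial markers, and the interferon score of its visceral fat was 10.82 against 8.17, 8.54 and 8.6. The macrophage score was 7.33 in the hypothalamus of low glucose, high weight replicate 1.

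In liver, low glucose, high weight replicate 4 had scores of 5.12 for lymphocyte markers, 12.64 for lipogenesis and 11.64 for hepatic glucose use, and replicate 2 of that group had 4.32 for female-biased genes and a Cyp2b10 value of 107. Replicate 1 of that group had Igkc at 110. High glucose, high weight replicate 4 had a branched-chain breakdown score of 11.51 and Acot2 at 311, replicate 1 had Fabp5 at 261, and replicate 2 had Scd1 at 44368, the other replicates reaching down to 787.

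In muscle, high glucose, high weight replicate 4 had an erythrocyte score of 10.5 and replicate 3 a slow fibre score of 7.55. In visceral fat of high glucose, high weight males, replicate 2 had Sparc at 90353, replicate 3 had Slc2a4 at 4550 and replicate 4 had Pcca at 1994.

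Over all tissues camera called 25 lists for the interaction of glucose and weaning weight and 33 for that of weaning weight and sex, and 0 of either held with an estimated correlation. In visceral fat 9 lists were called for glucose by weaning weight. A rule set after the values were seen, that at least 0.5 of members pass over the list alone, kept 5 of these: macrophage markers (adjusted p = 6.02e-06, 8 of 16 downward over the list alone), lipid-associated macrophage genes (adjusted p = 2.01e-08, 13 of 14), collagens (adjusted p = 4.25e-08, 13 of 18), cell cycle (adjusted p = 3.23e-06, 14 of 15) and cholesterol synthesis (adjusted p = 6.02e-06, 12 of 19). The others were branched-chain breakdown (adjusted p = 2.51e-06), endothelial markers (0.000584), adipocyte identity (0.00519) and erythrocyte markers (0.0264). With an estimated correlation erythrocyte markers had an adjusted p of 0.547 and the rest 0.511. Branched-chain breakdown was picked for its opposite signs in liver and muscle, so its permutation p of 0.00012 for that difference is no independent evidence.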

How the results depend on the processing

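Groups held 2 to 4 libraries, values were normalised and rounded, and list calls rested on a preset correlation, so calls near the threshold are uncertain. A count is the same within 1.5 times. A gene is reversed only where a call stands on either side, and a list only where the opposite direction is called. The planned DESeq2 test and the change between RLE and TMM factors were not run, as both need raw counts. The cause of each change was not tested.

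Weaning weight in males, with 1 gene in hypothalamus in the standard test, gave 0 genes there with the high glucose class alone, the low glucose class alone, males only in the fit and a pseudocount of 10. Glucose in males, with 440 genes in liver, 3 in muscle and 771 in visceral fat, gave 234, 1 and 4083 with the high weaning weight class alone and 9, 0 and 1 with the low weaning weight class alone. With males only in the fit muscle gave 0 and visceral fat 511 (107 higher, 404 lower). With females only in the fit, weaning weight in females gave 1 in hypothalamus in place of 0.

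With the replicate number of the titles as a replicate block, weaning weight in males gave 0 in hypothalamus and glucose gave 173 in visceral fat (25 higher, 148 lower). Replicate numbers did not pair libraries within a tissue.

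Without a filter on low values, weaning weight in females gave 1 in hypothalamus, 12 in liver and 11 in visceral fat, weaning weight by sex gave 1 in liver, and sex gave 586 in hypothalamus (277 higher, 309 lower) in place of 909. Weaning weight in males then gave 2 in subcutaneous and 1 in visceral fat, and glucose by weaning weight gave 1 in visceral fat.

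Without the trend and robust options, sex gave 220 in hypothalamus (101 higher, 119 lower), and glucose gave 277 in liver, 1 in muscle and 453 in visceral fat. Weaning weight in females and weaning weight by sex each gave 4 in liver, weaning weight by sex 2 in visceral fat, and weaning weight in males and glucose by weaning weight 1 each in visceral fat.

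The same total per library gave 1 gene for weaning weight in females in liver, and for glucose 6 in muscle and 1531 in visceral fat. Quantile normalization gave 1 gene for glucose by weaning weight in visceral fat, and Myh4 between the sexes in muscle reversed to 0. Without the library farthest from its group mean, visceral fat gave 1595 genes for glucose, 10 for weaning weight in males and 3532 for glucose by weaning weight.

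Of 209 list calls, 2 held with an estimated correlation and 19 with fry. Lists that reversed were collagens with glucose in visceral fat (adjusted p = 0.00934, low weaning weight class alone) and cholesterol synthesis with weaning weight in males in visceral fat (adjusted p = 0.0145, low glucose class alone). Without high glucose, high weight replicate 1, branched-chain breakdown (adjusted p = 0.0335) and adipocyte identity (adjusted p = 0.0207) reversed with glucose in subcutaneous fat, and without low-weight female replicate 2 cell cycle genes reversed with weaning weight in females in visceral fat (adjusted p = 0.016). Over such fits adjusted p ran from 1.71e-08 to 0.116 for the list branched-chain amino acid breakdown, glucose, males, subcutaneous adipose tissue. It ran from 9.83e-07 to 0.376 for the list adipocyte identity, glucose, males, subcutaneous adipose tissue, and from 7.92e-11 to 0.305 for the list cell cycle genes, weaning weight, females, visceral adipose tissue.

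Leaving out 1 library at a time gave these lowest and highest counts. They include fits that left 1 library in a group of 2, whose counts are uncertain. For glucose in males these were 0 and 3 in hypothalamus, 190 and 563 in liver, 1 and 5 in muscle, 0 and 0 in subcutaneous fat and 204 and 1595 in visceral fat. For weaning weight in males they were 0 and 1 in hypothalamus, 0 and 1 in liver, 0 and 0 in muscle and subcutaneous fat, and 0 and 10 in visceral fat. For weaning weight in females they were 0 and 2 in hypothalamus, 0 and 4 in liver, 0 and 1 in muscle, 0 and 0 in subcutaneous fat and 0 and 3 in visceral fat. For glucose by weaning weight they were 0 and 1 in hypothalamus, 0 and 0 in liver and muscle, and 0 and 3532 in visceral fat. For weaning weight by sex they were 0 and 2 in hypothalamus, 0 and 4 in liver, 0 and 0 in muscle and subcutaneous fat, and 0 and 2 in visceral fat. For sex they were 265 and 2148 in hypothalamus, 2001 and 3345 in liver, 986 and 1390 in muscle, 3623 and 8613 in subcutaneous fat, and 920 and 2584 in visceral fat.

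Named genes kept their call in every such fit for 24 of 36 liver and 14 of 34 visceral fat genes with glucose. Named glucose calls were 36 in liver, 2 in muscle and 34 in visceral fat, and of these 65 were lost in the low weaning weight class alone and 21 in the high weaning weight class alone. Liver Scd1 lost its call without a filter, with the replicate block, with males only and without the farthest library. Muscle Ivd and Mettl21e lost theirs with males only and without the trend and robust options, and Sparc in visceral fat with quantile normalization. Mmp14, Sparc and Thrsp in visceral fat and Ivd in muscle lost theirs with the replicate block.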

Other observations

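In visceral fat, gene lists of macrophages and matrix had glucose effects of opposite sign in the weaning weight classes, while 0 genes passed the interaction test. These lists rest on few libraries: the high-glucose, low-weight group held 2. The interaction gave 3532 genes without high glucose, high weight replicate 2. Within low-weight males, lipid-associated macrophage genes stood higher with high glucose (median 1.378, 10 members upward over the list alone; camera adjusted p = 4.4e-10, adjusted p = 0.374 with an estimated correlation), and macrophage markers had a median of 0.802 (camera adjusted p = 6.62e-05, adjusted p = 0.581 with an estimated correlation). Within high-weight males the same lists had medians of -1.044 (camera adjusted p = 0.00185, adjusted p = 0.82 with an estimated correlation) and -0.805 (camera adjusted p = 0.00241, adjusted p = 0.844 with an estimated correlation). Collagen and matrix genes fell in 12 of 18 members within high-weight males (median -1.168; camera adjusted p = 1.11e-05, adjusted p = 0.82 with an estimated correlation), and 8 of 11 endothelial markers rose (camera adjusted p = 4.21e-05, adjusted p = 0.82 with an estimated correlation). Within low-weight males collagens had a median of 0.279 (camera adjusted p = 0.00934, adjusted p = 0.692 with an estimated correlation). Cell cycle genes had medians of -1.507 within high-weight males (camera adjusted p = 4.21e-05, adjusted p = 0.82 with an estimated correlation) and 0.539 within low-weight males (camera adjusted p = 0.0135, adjusted p = 0.71 with an estimated correlation). Adipocyte identity genes had a median of -0.386 within low-weight males (camera adjusted p = 3.47e-06, adjusted p = 0.374 with an estimated correlation), of 0.173 within high-weight males, where the list did not pass (camera adjusted p = 0.767), and of 0.492 in the difference between the classes (camera adjusted p = 0.00519, adjusted p = 0.511 with an estimated correlation). Lipogenesis genes had a median of -0.475 within low-weight males (camera adjusted p = 2.17e-08, adjusted p = 0.152 with an estimated correlation). Within high-weight males they went the same way (median -0.371; camera adjusted p = 0.00247, adjusted p = 0.82 with an estimated correlation). The difference between the classes was not called for this list (camera adjusted p = 0.894).

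Tests chosen after the result was seen were the liver against muscle comparison and the overlap of lipogenesis genes.

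Branched-chain breakdown genes went up with high glucose in liver, by a mean of 0.2, and down in muscle, by -0.15, a difference of 0.35. Moving the glucose labels within each tissue gave a permutation p of 0.00012. Moving them by presumed animal over all 1400 assignments gave an exact permutation p of 0.0014, the smallest possible. No label names the animal, so that step rests on an inference. The list was picked because of its opposite signs, so these p values retest the pattern that chose it. Respiratory chain genes also had medians of opposite sign, 0.139 in liver and -0.174 in muscle, and nothing ties the pattern to this pathway alone.

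Lipogenesis genes past the threshold with glucose numbered 4 in liver and 9 in visceral fat, and 0 were shared among 20 genes (exact hypergeometric p = 1 for more sharing than independent calls would give). Calls on either side of a threshold do not test whether the genes differ between the tissues.

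The interferon deviations of the tissues correlated in several of 10 tissue pairs (permutation p, Benjamini-Hochberg over the 10 pairs). Libraries were matched by group and code number, presumed to mark 1 animal. Hypothalamus and muscle had a Pearson r of 0.93 (adjusted p = 5e-05; Spearman 0.87, adjusted p = 1e-04; r without the 2 farthest 0.85), and muscle and visceral fat 0.91 (adjusted p = 5e-05; Spearman 0.81, adjusted p = 0.0011; without the 2 farthest 0.9). Muscle and subcutaneous fat had 0.43 (adjusted p = 0.13; Spearman 0.36, adjusted p = 0.21; without the 2 farthest 0.03). High glucose, high weight code 2 had the largest deviations of hypothalamus, 0.75, and of visceral fat, 1.79, and in liver it was at 0.64, where code 1 of its group was at -1.29. An infection or immune state of single animals could produce such a pattern, given the shared-animal p of 1e-05, and neither was measured.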
